A study of Mus musculus with 8 samples.

How the data were processed

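Gene expression was measured on 8 Affymetrix mouse arrays, 1 per sorted sample. Per the labels' protocols, the mammary epithelial cells came from WT glands and from glands with a germline C/EBPb knockout, in 2 paired sets with 10 mice per group. They were FACS-sorted by CD24, CD29 and LIN. The same protocols name the Arcturus PicoPure kit for RNA isolation, a NuGEN FFPE kit for mRNA amplification and the Affymetrix protocol for biotin-labelled cRNA. The labels give 4 groups of 2 biological replicates: wildtype (WT) and knockout (KO), each as LIN-CD24+CD29hi cells (CD29hi below) and LIN-CD24hiCD29lo cells (CD29lo below). The mice behind each array, the sort purity and the part of Cebpb that was deleted are not given in the sources used here.

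The deposited values are 1 number per probe set and array on a log2 scale, floored at 0. The scale was read from the values, which run from 0 to at most 14.42. The array medians lie between 5.45 and 5.67, so the authors' processing had scaled the arrays to each other, by a method not given in the sources used here. No further normalization was applied. Raw scans were not used here, so the number of arrays limits the precision. A background was set per array at the 95th percentile of 27 control probe sets for bacterial genes, a choice made after the values had been seen. It lies between 3.84 and 4.41. Where both arrays of a group were at or below it, the fold is given against the background as a lower bound ("at least"). For the averaged contrast only the groups at or below the background were raised to it. Medians of lists are also given with such groups raised to the background where this moved them.

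Of the 45101 probe sets, 34958 carry 1 gene in the platform's annotation table, which dates from 2016, 932 carry several genes and 9211 carry none. Of the single-gene probe sets, 34754 matched a gene ID in a RefSeq gene table of assembly GRCm38, which served for names only. Each of the 18194 genes was represented by its probe set with the highest mean over the 8 arrays. Genes under the 25th percentile of all probe set means (3.51) were not tested, which left 14598 genes.

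Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit on the 4 groups and eBayes with a trend of the variance on the mean. The fit has 4 residual and 4.31 prior degrees of freedom. It gave 6 two-sided contrasts: KO against WT in CD29hi, in CD29lo and averaged over both, the difference between the genotype contrasts (interaction), and CD29hi against CD29lo in each genotype. P values were adjusted by Benjamini-Hochberg over all genes within a contrast, with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Log2 fold changes are given with their standard error as log2 fold change ± SE, and group means with their SD and n = 2.

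For gene groups, 27 lists were written before the data were examined: mammary lineages, signalling pathways, C/EBP family members and targets, genes that neighbour Cebpb on its chromosome, cell cycle, interferon, tissue dissociation stress and markers of other cell types. They hold 590 different genes, of which 556 have a value, and some genes belong to several lists. Each list was tested against all other genes with camera (correlation preset at 0.01), adjusted over the 27 lists within a contrast. Camera with an estimated correlation and fry were run beside it. Fry is given for its directional test only, which is not made for lists whose genes moved both ways. For list members, the count adjusted over all genes is given beside the count adjusted over the list alone.

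The genes named in the text follow a rule fixed before the data were examined. For each contrast these are Cebpb, the 10 largest rises and 10 largest falls past the threshold whose groups do not overlap, filled up by the smallest p where fewer passed, and up to 4 members of each list with the smallest p. For the interaction they are the 5 genes of smallest p in each direction. The text gives a selection of them.

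The alternatives fixed before the data were examined were quantile normalization, no filter, a filter at the 50th percentile, every probe set tested, the mean of all probe sets per gene, eBayes without a trend, array weights, only the arrays compared, the replicate number as a block, the pool of glands as a random block, and leaving out each array in turn. For the random block, arrays of 1 genotype with the same replicate number were assumed to be 1 pool. Where an array is left out, its group keeps 1 array, which is assumed to vary like the other groups. A floor before log2 was planned for linear values only and does not apply. Added after the data had been seen were values raised to at least 4, both CD29lo arrays numbered 2 left out together, and the mean of the fibroblast list as a covariate.

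The fit was tested on simulated data with independent genes, the spread of the 14598 genes and no structure between arrays. In 5 runs per design, 200 genes were changed by a log2 value of 1, 2 or 4. For KO against WT in CD29hi the fit recovered 11.6%, 48.4% and 80.3% of them, and 4.12% of its calls were false. For KO against WT in CD29lo it recovered 10.7%, 44.8% and 82.7%, with 4.57% false. For the averaged contrast it recovered 25.4%, 69.3% and 92.4%, with 2.96% false. For the interaction it recovered 5.97%, 16.7% and 60.3%, with 2.83% false. For CD29hi against CD29lo it recovered 13.1%, 46.9% and 84.5% in WT, with 4.76% false, and 14.3%, 49.6% and 84.5% in KO, with 5.37% false. The changed genes were drawn without regard to the lists. Over the 5 runs, camera still called 1 list in CD29hi, 2 in CD29lo and 1 in the averaged contrast, while fry called 6, 5 and 9.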

Results

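RNA was measured in FACS-sorted mammary epithelial cells of wildtype and germline C/EBPb knockout mice, in 4 groups of 2 arrays. The series set out to find pathways that C/EBPb, a transcription factor, regulates in these stem and progenitor subpopulations. In each array between 64.74% and 71.16% of the probe sets lay above the background. The first principal component carried 54.1% of the variance and separated CD29hi from CD29lo, the second 13.6% and the third 9.61%. The second set KO CD29lo replicate 1 (score 64.6) and WT CD29lo replicate 2 (-56.2) apart from their own replicates (-17.7 and 8.30). KO CD29lo replicate 1 also had the highest background (4.41) and the smallest share of probe sets above it (64.74%). The correlation between arrays of 1 group was 0.954 in KO CD29hi, 0.95 in WT CD29hi, 0.947 in WT CD29lo and 0.931 in KO CD29lo. Some arrays correlated more with an array of the other genotype in the same gate than with their own replicate, among them both KO CD29lo arrays with WT CD29lo replicate 1 (0.95 and 0.944) and WT CD29hi replicate 1 with KO CD29hi replicate 1 (0.951).

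Cebpb itself was lower in every knockout array than in every wildtype array. Its brighter probe set read 11.95 and 12.25 in WT CD29hi, 8.6 and 9.38 in KO CD29hi, 11.83 and 12.18 in WT CD29lo, and 9.23 and 8.89 in KO CD29lo. The log2 fold change was -3.11 ± 0.274 in CD29hi (limma adjusted p = 0.0177) and -2.95 ± 0.274 in CD29lo (limma adjusted p = 0.0271). The residual Cebpb signal stayed above the background in all 4 knockout arrays. The other probe set was dim, between 2.25 and 4.61, and did not pass. The labels do not say which part of the gene was deleted, so a probe set outside that part would check nothing.

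In CD29hi cells Them5 was called lower in the knockout beside Cebpb. Them5, an acyl-CoA thioesterase gene, stood at 8.28 ± 0.368 (SD, n = 2) in WT and below the background in KO. It was thus at least 20.9-fold lower (limma adjusted p = 0.00594). Among the genes of next smallest p, none of which passed, were the mitotic genes Kif20b (at least 10.9-fold lower, adjusted p = 0.0714), Kif11 (-3.89, adjusted p = 0.104), Ckap2 (at least 6.63-fold lower) and Cenph (at least 9.42-fold lower). The lipid droplet gene Plin2 (-1.88, adjusted p = 0.104) and the casein gene Csn1s1 (at least 3.66-fold lower, adjusted p = 0.104) belonged to them too. Klf4 (0.93, adjusted p = 0.147), Zfhx3 (1.01) and Gcnt1 (1.75) had the smallest p among higher genes, and none passed. Of 14598 genes, 0 were called higher and 2 lower by limma, while 1145 had an unadjusted p under 0.05 against 730 from chance. The Them5 call was lost without WT CD29hi replicate 1 (adjusted p = 0.0635) or replicate 2 (adjusted p = 0.224), and with the mean of its probe sets (0.115). The Cebpb call was lost without WT CD29hi replicate 1 (adjusted p = 0.139), WT CD29hi replicate 2 (0.52), WT CD29lo replicate 1 (0.0621) or WT CD29lo replicate 2 (0.0574), and the count then was 1, 0, 1 and 1. It was also lost without a trend (0.213) and with the mean of probe sets (0.226).

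Cell-cycle genes were the gene group that was lowest in knockout CD29hi cells. The list's median log2 fold change was -1.25, with 31 of 35 members below 0 (camera adjusted p = 4.02e-16; adjusted p = 0.534 with an estimated correlation). The 14 members with a mean log2 of 7 or more had a median of only -0.43. The proliferation marker Mki67 stood at -3.26, the spindle factor Tpx2 at -3.57 and Birc5 at -3.41. Over all genes 0 members passed, while 18 were lower and 1 higher when adjusted over the list alone. Luminal progenitor and alveolar genes were also lower, with a median of -0.66 (camera adjusted p = 0.000628; adjusted p = 0.539 with an estimated correlation). Among them were Elf5 (-3.19), the alveolar transcription factor, lactoferrin (Ltf, -2.16) and the casein gene Csn3 (-1.80). Over all genes 0 of these 17 members passed, and 3 were lower when adjusted over the list alone. The dissociation stress list, which holds immediate early genes such as Atf3 (0.81) and Fosb (0.83), was higher with a median of 0.20 (camera adjusted p = 3.28e-05; adjusted p = 0.539 with an estimated correlation), with 0 members over all genes and 1 when adjusted over the list alone. Blood cell markers were higher with a median of 0.49, or 0.28 with groups below the background raised to it (camera adjusted p = 0.0461; adjusted p = 0.539 with an estimated correlation), with 0 members over all genes and 0 when adjusted over the list alone. That last call was lost without KO CD29hi replicate 2 (0.288), KO CD29lo replicate 1 (0.0546) or 2 (0.0527), or WT CD29hi replicate 1 (0.0993) or 2 (0.0664). It was also lost with array weights (0.0502), the mean of probe sets (0.0573), only the arrays compared (0.0605), quantile normalization (0.0699), the filter at the 50th percentile (0.0956) and no filter (0.243). Of the added settings, both CD29lo arrays numbered 2 left out (0.0569), the fibroblast covariate (0.0639) and values raised to 4 (0.0917) ended it as well. The other 3 lists passed whichever array was left out, and fry called 0 lists. The progenitor median was -0.33 without KO CD29hi replicate 1, -1.14 without KO CD29hi replicate 2 and -0.41 without WT CD29hi replicate 2, where the dissociation stress median was 0.13.

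**Figure D1:**
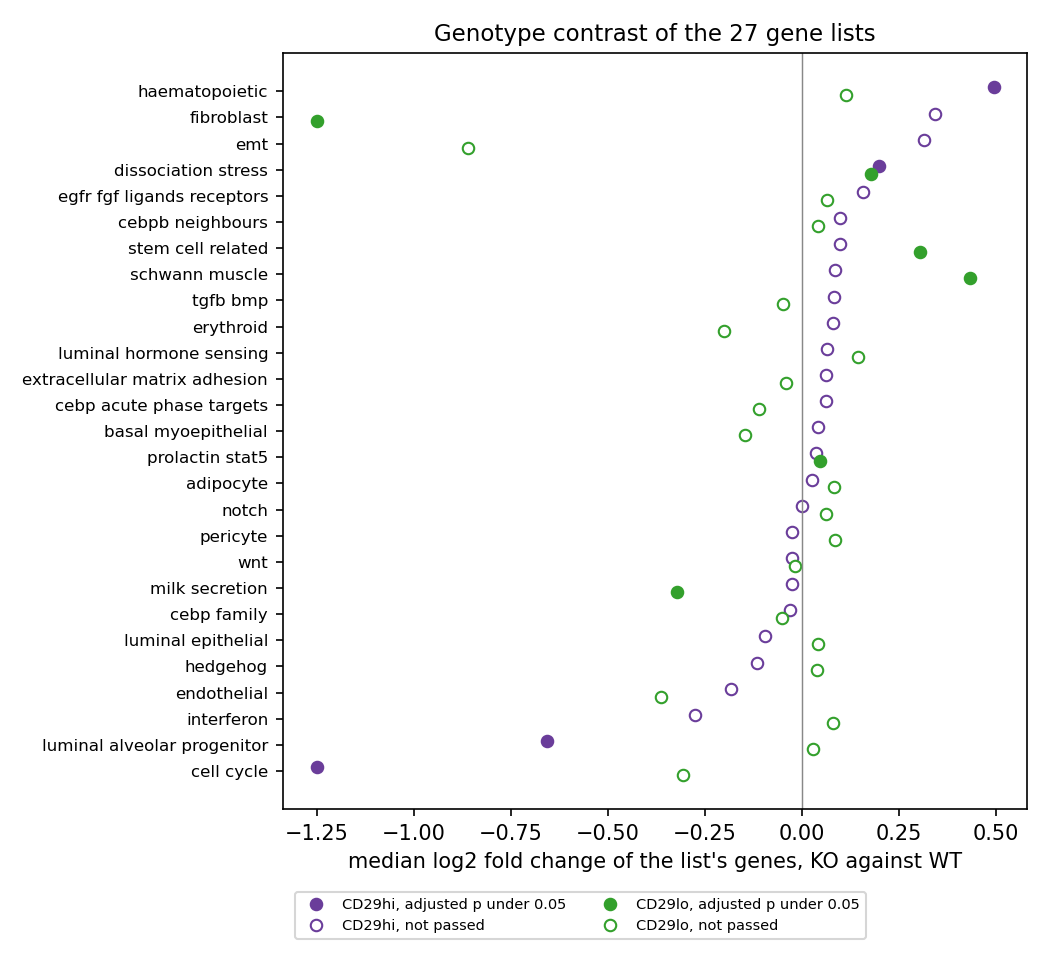
Median log2 fold change of each of the 27 gene lists, KO against WT, in CD29hi (purple) and CD29lo (green). Filled points have a camera adjusted p under 0.05 with the preset correlation; cell-cycle genes lie at -1.25 in CD29hi (-0.43 over the 14 brighter members) and fibroblast markers at -1.25 in CD29lo.

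In CD29lo cells the milk protein gene Csn1s1 was called lower in the knockout beside Cebpb. Csn1s1 stood at 7.55 in WT and below the background in KO, at least 9.57-fold lower (limma adjusted p = 0.0271). The caseins Csn2 (at least 5.11-fold, adjusted p = 0.16) and Csn1s2a (at least 17.5-fold, adjusted p = 0.307), the protease inhibitor Slpi (-4.70, adjusted p = 0.0573) and the acute phase gene Saa1 (-3.29, adjusted p = 0.334) were lower without passing. Cdcp3 (3.27, adjusted p = 0.0573), Rtn1 (2.11) and Ssc4d (3.25) were higher without passing. Of 14598 genes, 0 were called higher and 2 lower by limma, while 975 had an unadjusted p under 0.05. Csn1s1 lost its call without KO CD29hi replicate 1 (adjusted p = 0.0517), KO CD29lo replicate 1 (0.0784) or 2 (0.0741), WT CD29hi replicate 1 (0.135) or 2 (0.141), or WT CD29lo replicate 1 (0.243) or 2 (0.494). It also lost it with only the arrays compared (0.146) or both CD29lo arrays numbered 2 left out (0.142). Cebpb lost its call without KO CD29lo replicate 1 (0.0784) or 2 (0.0741), WT CD29hi replicate 1 (0.145) or 2 (0.145), or WT CD29lo replicate 1 (0.243) or 2 (0.494), and also without a trend (0.256), with the mean of probe sets (0.241), only the arrays compared (0.0925) or both CD29lo arrays numbered 2 left out (0.167). The count was 0 without any of the 4 WT arrays and 1 without KO CD29hi replicate 1 or KO CD29lo replicate 2.

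Milk and secretion genes were lower as a group in knockout CD29lo cells, with a median log2 fold change of -0.32, or -0.23 with groups below the background raised to it (camera adjusted p = 0.0152; adjusted p = 0.627 with an estimated correlation). Over all genes 1 member passed, and 3 were lower when adjusted over the list alone. The group lost its call without KO CD29lo replicate 1 (0.0502, median -0.13), with the filter at the 50th percentile (0.393, median -0.17) and with the mean of probe sets (0.103). Fibroblast markers were lower in all 19 members, with a median of -1.25 (camera adjusted p = 0.0152; adjusted p = 0.829 with an estimated correlation), among them Fap (-2.15), Mfap5 (-1.42), Pdgfra (-1.37) and Serpinf1 (-0.96). Of these 0 passed over all genes and 0 when adjusted over the list alone. Their median turned to 0.425 without KO CD29lo replicate 1 and was -0.17 without WT CD29lo replicate 2, with adjusted p = 0.187 and 0.72. It was -2.98 without KO CD29lo replicate 2 and -2.31 without WT CD29lo replicate 1. They too lost their call with the filter at the 50th percentile (0.0516) and the mean of probe sets (0.0615), so neither lower list passed in these 2 settings. With the fibroblast covariate, which removes them by construction, it was 0.749. Dissociation stress genes such as Fosb (1.15) and Fos (0.66) were higher, with a median of 0.18 (camera adjusted p = 2.85e-06; adjusted p = 0.415 with an estimated correlation), with 0 members over all genes and 0 when adjusted over the list alone. The stress median was 0.10 without WT CD29lo replicate 1 and 0.28 without WT CD29lo replicate 2, where the milk median was -0.20.

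Stem cell related genes (median 0.30, or 0.29 with groups below the background raised to it), prolactin and STAT5 genes (0.05) and Schwann and muscle markers (0.43) were higher in knockout CD29lo cells, each with camera adjusted p = 0.0426 and adjusted p = 0.415 with an estimated correlation. Over all genes 0 members of each passed, with 0, 1 and 0 when adjusted over the list alone. Without KO CD29lo replicate 1 or 2, or WT CD29lo replicate 1, all 3 lists lost their calls, with adjusted p = 0.292, 0.0813 and 0.213 for stem cell related genes, 0.0823, 0.273 and 0.0946 for prolactin and STAT5 genes, and 0.0789, 0.275 and 0.0775 for Schwann and muscle markers. The prolactin and muscle lists also lost theirs without WT CD29lo replicate 2 (0.0878 and 0.171). The stem cell and prolactin lists lost theirs without KO CD29hi replicate 1 (0.0508 in both) or 2 (0.0513 in both), and the muscle list without WT CD29hi replicate 1 (0.052) or 2 (0.0524). With the mean of probe sets all 3 lost their calls (0.154, 0.154 and 0.171). The stem cell list also lost its call with the replicate number as a block (0.0581), only the arrays compared (0.0547) and the fibroblast covariate (0.0855), the prolactin list without a filter (0.281) and the muscle list with quantile normalization (0.0569). With the filter at the 50th percentile the muscle list kept too few genes to be tested. Both CD29lo arrays numbered 2 left out ended all 3 (0.0544, 0.243 and 0.431), and values raised to 4 ended the stem cell and prolactin calls (0.0944 and 0.128). Luminal progenitor genes (median 0.03, with 10 of 17 members above 0, camera adjusted p = 0.891) and cell-cycle genes (median -0.30, or -0.26 with groups below the background raised to it, camera adjusted p = 0.429) did not pass in CD29lo. Fry called 0 lists in CD29lo.

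Averaged over both subpopulations, 4 knockout arrays were compared with 4 wildtype arrays, and 9 genes fell and 1 rose in the knockout. In both KO groups 4 of the genes that fell lay below the background. Averaged over the gates these were at least 5.91-fold lower for Csn1s1 (limma adjusted p = 0.00326), at least 6.82-fold for Them5 (limma adjusted p = 0.00312), at least 3.92-fold for Csn2 and at least 5.99-fold for Kif20b. The others were Cebpb (-3.03 ± 0.194, limma adjusted p = 0.00277), Slpi (-3.91), the proton pump subunit gene Atp6v1c2 (-3.73), the inflammatory caspase gene Casp1 (-2.35) and Golim4 (-1.09). Cdcp3 rose by 2.13 (limma adjusted p = 0.0421). The calls of Cebpb, Csn1s1 and Them5 held whichever array was left out, with adjusted p of at most 0.0439, 0.044 and 0.0439. Casp1 and Cdcp3 lost theirs in all 8 of these fits, with adjusted p up to 0.315 and 0.205. Csn2 kept its call only without KO CD29lo replicate 2, Atp6v1c2, Golim4 and Slpi only without KO CD29lo replicate 1 or 2, and Kif20b only without those arrays or KO CD29hi replicate 1. For these 5 genes, in the order Csn2, Atp6v1c2, Golim4, Slpi and Kif20b, the adjusted p was largest without WT CD29hi replicate 2: 0.284, 0.284, 0.327, 0.178 and 0.19. The count of 10 was 3 without KO CD29hi replicate 2, WT CD29hi replicate 2, WT CD29lo replicate 1 or WT CD29lo replicate 2, 4 without WT CD29hi replicate 1, 6 without KO CD29hi replicate 1 and 21 without KO CD29lo replicate 2. Without a trend Csn2 (0.132), Slpi (0.11), Atp6v1c2 (0.134), Casp1 (0.125), Golim4 (0.2) and Cdcp3 (0.0608) lost their calls. With the filter at the 50th percentile Atp6v1c2, Casp1, Golim4 and Cdcp3 lost theirs (0.0523 each), and Csn1s1, Them5, Csn2 and Kif20b were too dim to be tested. With the mean of probe sets Csn2 (0.186), Kif20b (0.289) and Golim4 (0.0649) lost theirs, with every probe set Csn2 (0.0516), Casp1, Golim4 and Cdcp3 (0.0569 each), without a filter Casp1 (0.051) and Cdcp3 (0.0518), and with quantile normalization Golim4 (0.0674). Values raised to 4 ended the calls of Csn2 (0.155), Casp1 and Cdcp3 (0.0505 each). Leaving out both CD29lo arrays numbered 2 ended those of Csn1s1 and Atp6v1c2 (0.0529 each), Csn2 and Kif20b (0.097 each), Casp1 (0.0995), Golim4 (0.0963) and Cdcp3 (0.15). At an unadjusted p under 0.05 there were 1353 genes.

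**Figure D2:**
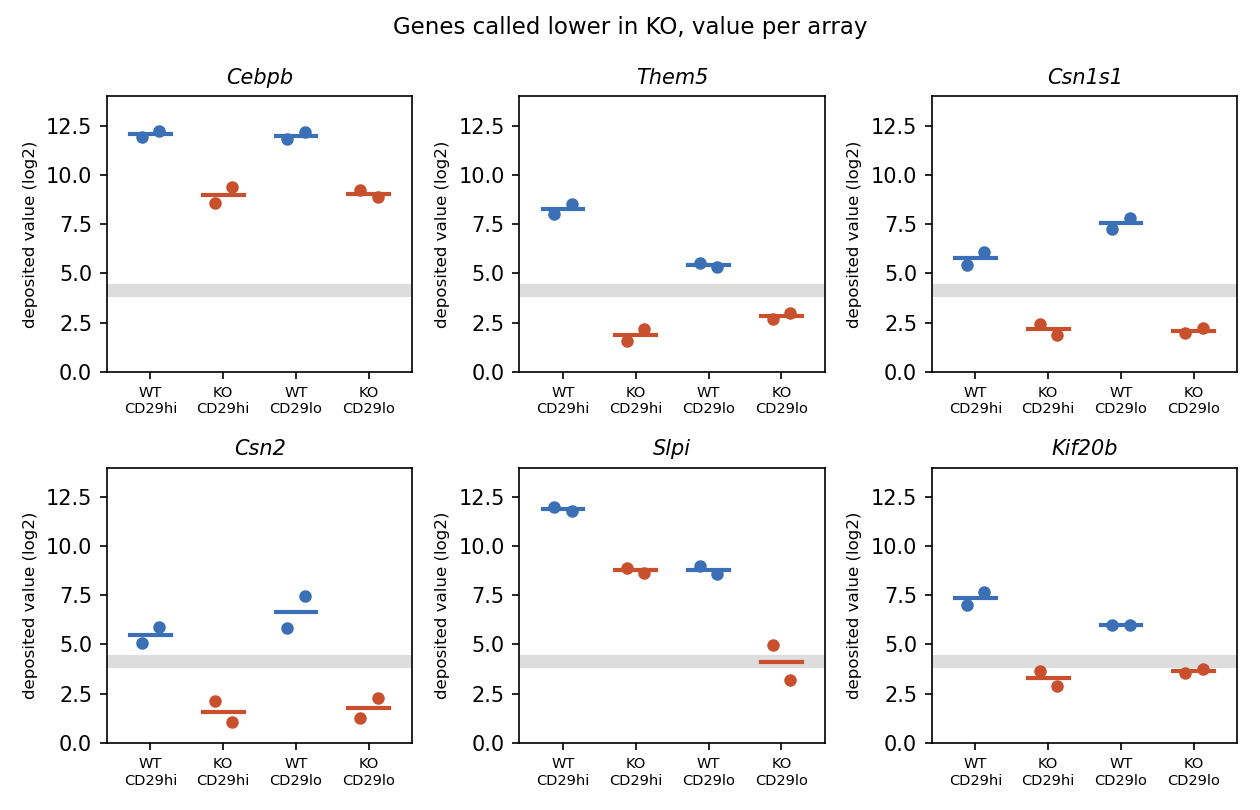
Deposited log2 value of 6 genes that were lower in the averaged contrast, per array (points) with group means (bars), in WT (blue) and KO (red). The grey band spans the background of the 8 arrays, 3.84 to 4.41; Csn1s1 and Csn2 lie below it in all 4 KO arrays.

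By list, cell-cycle genes (median -0.73, camera adjusted p = 7.74e-10), milk genes (-0.24, camera adjusted p = 0.0107) and luminal progenitor genes (-0.41, camera adjusted p = 0.0188) were lower in the averaged contrast. The cell-cycle and progenitor lists passed in CD29hi, but neither passed in CD29lo (camera adjusted p = 0.429 and 0.891, medians -0.30 and 0.03). This alone does not show that the gates differ. In the interaction camera with the preset correlation called both lists, though the progenitor call did not hold whichever array was left out. With an estimated correlation no list passed there (smallest camera adjusted p = 0.676). That variant called 0 lists in all 6 contrasts, basal markers between the gates included, so its failure does not show that the gates agree. In the averaged contrast the 3 lower lists had adjusted p = 0.345, adjusted p = 0.443 and adjusted p = 0.496 with an estimated correlation. Over all genes 0, 2 and 0 members passed, and 15, 5 and 1 were lower when adjusted over the list alone, where 1 cell-cycle gene was higher. Without WT CD29hi replicate 2 the cell-cycle median was -0.46 and the dissociation stress median 0.13, and with the filter at the 50th percentile the milk median was -0.73. Dissociation stress genes (median 0.20, camera adjusted p = 5.19e-09), blood cell markers (0.23, 0.0471) and stem cell related genes (0.14, 0.0471) were higher, each with adjusted p = 0.345 with an estimated correlation. With groups below the background raised to it, the medians of the last 2 were 0.13 and 0.12. Over all genes 0 members of each passed, with 5, 0 and 2 when adjusted over the list alone. The milk call was lost without KO CD29hi replicate 1 (0.0531, median -0.01) or WT CD29hi replicate 2 (0.0567, median -0.12), and with the mean of probe sets (0.0849, median -0.05). The progenitor call was lost without KO CD29hi replicate 1 (0.13), KO CD29lo replicate 2 (0.0968), WT CD29hi replicate 2 (0.0799) or WT CD29lo replicate 1 (0.103), or both CD29lo arrays numbered 2 (0.0518). With the replicate number as a block the blood cell (0.061) and stem cell (0.0637) calls were lost, so 1 of the 3 higher lists then passed. Both were also lost with the mean of probe sets (0.0849 and 0.177), no filter (0.322 and 0.0658) and values raised to 4 (0.348 and 0.108). The blood cell call was further lost with every probe set (0.0873) and both CD29lo arrays numbered 2 left out (0.0869), and the stem cell call with the fibroblast covariate (0.056). The stem cell call was lost without KO CD29hi replicate 1 (0.0686) or 2 (0.0702), KO CD29lo replicate 1 (0.127) or 2 (0.0665), WT CD29hi replicate 1 (0.154) or 2 (0.0567), or WT CD29lo replicate 1 (0.103). The blood cell call was lost without KO CD29hi replicate 2 (0.23), KO CD29lo replicate 1 (0.0649) or 2 (0.119), WT CD29hi replicate 1 (0.0625) or 2 (0.0902), or WT CD29lo replicate 1 (0.103).

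The other lists did not pass in either genotype contrast, and their medians in CD29hi and CD29lo follow. Basal markers stood at 0.04 and -0.14, luminal epithelial markers at -0.10 and 0.04, and hormone-sensing luminal markers at 0.07 and 0.15. C/EBP family members stood at -0.03 and -0.05, and acute phase and C/EBP target genes at 0.06 and -0.11. Notch genes stood at 0.00 and 0.06, Wnt genes at -0.03 and -0.02, Hedgehog genes at -0.12 and 0.04, TGF-beta and BMP genes at 0.08 and -0.05, and EGF and FGF ligands and receptors at 0.16 and 0.07. Genes of the epithelial to mesenchymal transition stood at 0.32 and -0.86, interferon genes at -0.28 and 0.08, and matrix and adhesion genes at 0.06 and -0.04. Endothelial markers stood at -0.18 and -0.36, pericyte markers at -0.03 and 0.09, adipocyte markers at 0.03 and 0.08, and erythroid markers at 0.08 and -0.20. The chromosomal neighbours of Cebpb stood at 0.10 and 0.04. With groups below the background raised to it, hormone-sensing markers turned to -0.04 in CD29hi, where mesenchymal transition genes stood at 0.23. In CD29lo adipocyte markers then stood at 0.20, Hedgehog genes at 0.12, EGF and FGF genes at 0.10, basal markers at -0.08 and TGF-beta genes at -0.01. Interferon genes in CD29hi (-0.26) and mesenchymal transition genes in CD29lo (-0.84) moved little. Signs differed between the measures for some of these lists. In CD29hi the acute phase, Notch and basal lists had a mean and a camera direction below 0 beside a median at or above 0. There the Hedgehog list had only its mean above 0, the endothelial list only its median below 0, the prolactin list only its mean below 0 and the erythroid list only its camera direction below 0. In CD29lo the progenitor list had only its median above 0, the TGF-beta and matrix lists only their camera direction above 0, and the blood cell and neighbour lists only their mean below 0. Each list called by camera in any contrast had a median, a mean and a test of the same sign there. Milk genes in CD29hi had a median of -0.03, a mean of -0.77 and camera adjusted p = 0.0515, and fibroblast markers there a median of 0.35 and camera adjusted p = 0.383.

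Whether the genotype contrast differed between the subpopulations was tested by the interaction, in which no named gene passed. The smallest p belonged to Col13a1 (4.38) and Sncg (3.42), which were relatively higher in knockout CD29hi cells, and to Them5 (-3.82) and Slc22a5 (-2.62), which were relatively lower. Col13a1 in WT CD29hi and Them5 in both KO groups lay below the background, so these 2 fitted values are no measure of size. Of 14598 genes 0 were called by limma (smallest adjusted p = 0.95), and 722 had an unadjusted p under 0.05 against 730 from chance. Across genes, which are not independent replicates, the genotype fold changes in CD29hi and CD29lo correlated with Pearson r = 0.159 and Spearman rho = 0.129. At an unadjusted p under 0.05 in both there were 167 genes, 136 of them in the same direction. Of these, 77 were lower in both and 59 higher in both, against 29.4 and 11 if the contrasts were independent. The 2 contrasts share the variance estimate of each gene, which can raise the overlap above these values in either direction. It does not by itself favour the same direction, in which 136 of the 167 genes lay. Arrays of both gates may share mice, so genotype is not separated from other differences between the mice.

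Basal and myoepithelial genes separated the gates in both genotypes. In WT the keratin gene Krt5 was higher in CD29hi by 5.68 ± 0.211 (limma adjusted p = 3.32e-05) and smooth muscle actin (Acta2) by 4.58 ± 0.186 (limma adjusted p = 3.4e-05). In KO these differences were 4.98 and 5.03. The luminal genes Krt19 (-2.48), Cldn7 (-2.92), Foxa1 (-5.37), Pgr (-2.99) and Esr1 (-3.22) were lower in WT CD29hi. The Notch ligands Dll1 (4.17) and Jag1 (2.15) were higher, and Dtx4 (-3.03) and Wnt7b (at least 7.22-fold) lower. Of 14598 genes, 578 were higher and 618 lower in CD29hi in WT, and 1081 higher and 972 lower in KO. Of these genes 945 were called in both genotypes, all 945 in the same direction. The WT count of 1196 was 560 without WT CD29hi replicate 1, 512 without WT CD29hi replicate 2, 524 without WT CD29lo replicate 1 and 728 without WT CD29lo replicate 2. The KO count of 2053 was 722 without KO CD29hi replicate 1 and 1073 without KO CD29hi replicate 2.

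**Figure D3:**
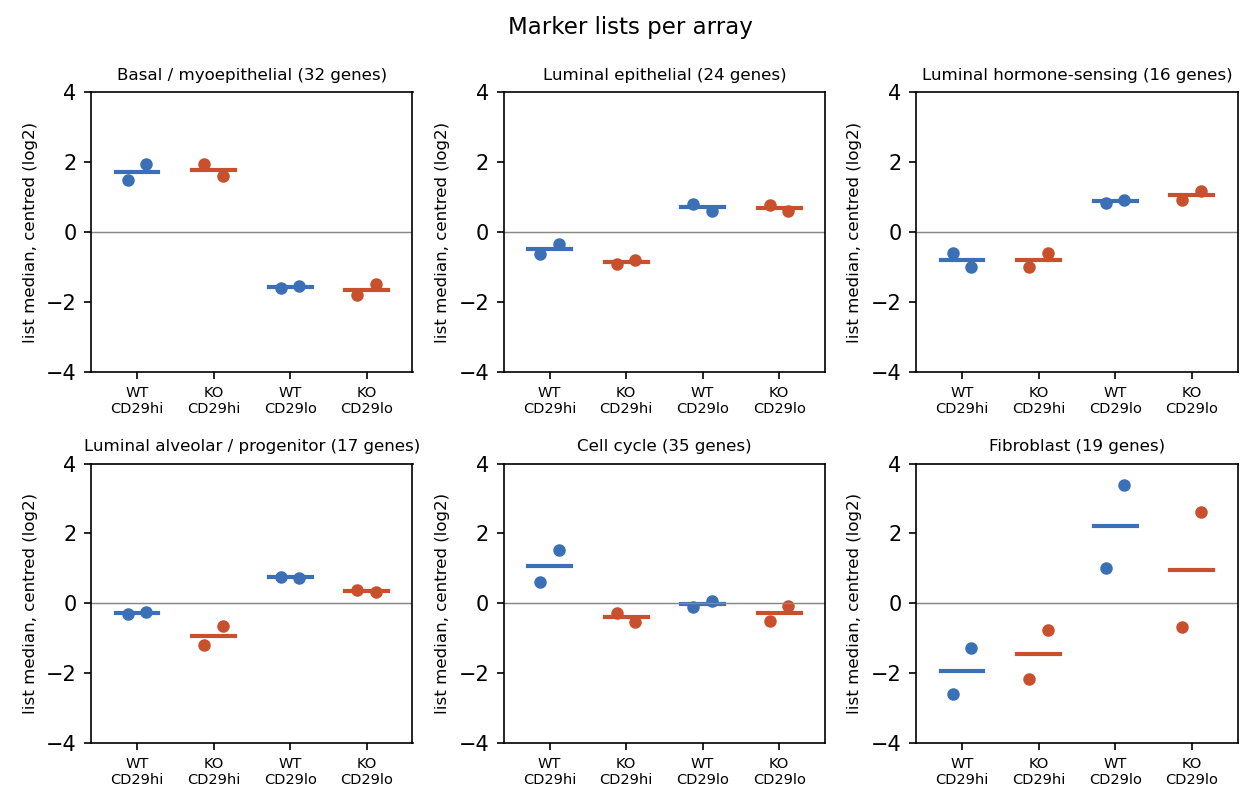
Median of each array's log2 values over 6 marker lists, each gene centred on its mean over the 8 arrays, with group means (bars), in WT (blue) and KO (red). Fibroblast markers range from -2.60 in a WT CD29hi array to 3.37 in WT CD29lo replicate 2.

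As groups, basal markers had a median of 3.44 in WT (camera adjusted p = 7.73e-21; adjusted p = 0.157 with an estimated correlation), with 18 higher and 1 lower over all genes and 22 and 1 when adjusted over the list alone. Luminal epithelial markers had a median of -1.23 (camera adjusted p = 1.24e-14; adjusted p = 0.157 with an estimated correlation), with 14 lower over all genes and 18 when adjusted over the list alone. Hormone-sensing markers stood at -1.98, or -1.53 with groups below the background raised to it (camera adjusted p = 9.47e-09; adjusted p = 0.262 with an estimated correlation), with 8 lower over all genes and 10 when adjusted over the list alone. Interferon genes such as Irf1 (-2.34) and Iigp1 (-3.94) stood at -1.92 (camera adjusted p = 2.8e-09; adjusted p = 0.262 with an estimated correlation), with 9 lower over all genes and 14 when adjusted over the list alone. Fibroblast markers such as Dcn (-4.82) and Col1a2 (-5.18) stood at -4.01, or -3.92 with groups below the background raised to it (camera adjusted p = 9.47e-09; adjusted p = 0.358 with an estimated correlation), with 8 lower over all genes and 15 when adjusted over the list alone. Col1a2 lost its call without WT CD29hi replicate 1 (adjusted p = 0.153) or 2 (0.0878) or WT CD29lo replicate 1 (0.0727) or 2 (0.136). Camera called 13 lists in WT and 11 in KO, and fry 11 and 14, but with an estimated correlation 0 lists passed in either genotype (smallest adjusted p = 0.157 and 0.139). In WT the matrix list (median 0.55) lost its call without WT CD29hi replicate 2 (0.169) or WT CD29lo replicate 1 (0.0681, median -0.01), and the Wnt list without WT CD29hi replicate 2 (0.053). The WT Hedgehog list lost its call without WT CD29hi replicate 1 (0.0911) or 2 (0.0802) or WT CD29lo replicate 2 (0.0528). The filter at the 50th percentile ended all 3 calls (0.061, 0.111 and 0.0753 for matrix, Wnt and Hedgehog genes), and the mean of probe sets the Hedgehog call (0.214). For the matrix, Wnt and Hedgehog lists in WT adjusted p = 0.486, adjusted p = 0.262 and adjusted p = 0.262 with an estimated correlation. Over all genes 8, 7 and 4 of their members were higher and 1 each lower, and 9, 11 and 6 were higher and 3, 3 and 1 lower when adjusted over the list alone.

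In KO the same lineage groups stood apart: basal markers at 3.54, luminal epithelial markers at -1.86 and hormone-sensing markers at -1.63. Their camera adjusted p values were 4.98e-17, 1.17e-15 and 5.96e-08, with adjusted p = 0.139, adjusted p = 0.139 and adjusted p = 0.284 with an estimated correlation. Over all genes 19 basal genes were higher and 2 lower, with 19 luminal epithelial and 9 hormone-sensing genes lower. When adjusted over the list alone 24 basal genes were higher and 2 lower, and 19 luminal epithelial and 10 hormone-sensing genes were lower, with 1 hormone-sensing gene higher. Luminal progenitor genes had a median of -0.61 in KO (camera adjusted p = 3.6e-05; adjusted p = 0.284 with an estimated correlation), with 8 lower over all genes and 9 when adjusted over the list alone. In WT the median was -1.03 (camera adjusted p = 0.000379; adjusted p = 0.262 with an estimated correlation), with 3 lower over all genes, and 8 lower and 1 higher when adjusted over the list alone. The KO median was -1.26 without KO CD29hi replicate 2 and -2.36 with the filter at the 50th percentile. Single members need not follow the medians: Ltf stood at -3.90 in KO and -2.07 in WT, and Csn3 at -3.92 and -2.07. In WT the Ltf call was lost without WT CD29hi replicate 2 (adjusted p = 0.08) or WT CD29lo replicate 1 (0.0666) or 2 (0.0503), and the Csn3 call without WT CD29hi replicate 1 (0.135) or WT CD29lo replicate 1 (0.112) or 2 (0.0892). Fibroblast markers in KO (median -2.59, or -2.40 with groups below the background raised to it) had camera adjusted p = 0.00081 but adjusted p = 0.637 with an estimated correlation, with 4 lower over all genes and 7 when adjusted over the list alone. Milk genes (-0.20, or -0.39 so raised) had camera adjusted p = 0.0395 but adjusted p = 0.419 with an estimated correlation, with 5 lower over all genes and 6 when adjusted over the list alone. Without KO CD29lo replicate 2 both lost their calls (0.243 and 0.103), and their medians were -0.98 and -0.05. Without KO CD29lo replicate 1 these were -4.01 and -0.36, and with the filter at the 50th percentile milk genes stood at -1.44. The milk call was also lost with only the arrays compared (0.0504), the mean of probe sets (0.0591), quantile normalization (0.0702, median -0.14) and the fibroblast covariate (0.213), and with both CD29lo arrays numbered 2 left out (0.125), where the fibroblast call was lost too (0.254).

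The remaining lists called between the gates follow. Cell-cycle genes were higher in CD29hi in WT, with a median of 1.30 (camera adjusted p = 0.00031; adjusted p = 0.327 with an estimated correlation), or 0.84 without WT CD29hi replicate 2. Over all genes 7 were higher and 1 lower, and 16 and 2 when adjusted over the list alone. In KO their median was -0.18, or -0.23 with groups below the background raised to it, and the list did not pass (camera adjusted p = 0.421). Acute phase and C/EBP target genes were lower, at -0.71 in WT (camera adjusted p = 0.000112; adjusted p = 0.266 with an estimated correlation) and -0.52 in KO (camera adjusted p = 0.00105; adjusted p = 0.364 with an estimated correlation). Over all genes 6 and 5 of them were lower, and 7 and 5 when adjusted over the list alone. Their medians were -1.24 without WT CD29lo replicate 1 in WT, -0.95 without KO CD29hi replicate 2 in KO, and -1.46 and -1.30 with the filter at the 50th percentile. Dissociation stress genes stood at -0.31 in WT (camera adjusted p = 4e-04; adjusted p = 0.262 with an estimated correlation) and -0.25 in KO (camera adjusted p = 0.00179; adjusted p = 0.333 with an estimated correlation). Over all genes 6 and 5 of them were lower and 1 each higher, and 8 and 9 lower and 1 each higher when adjusted over the list alone. In KO they stood at -0.15 without KO CD29lo replicate 1 and -0.39 with the mean of probe sets.

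Milk genes in WT stood at -0.67 (camera adjusted p = 0.000447; adjusted p = 0.262 with an estimated correlation), with 3 lower over all genes and 5 when adjusted over the list alone. They stood at -1.12 without WT CD29hi replicate 2 and -0.43 without WT CD29lo replicate 2. Wnt genes in WT stood at 0.34, or 0.40 with groups below the background raised to it, and Hedgehog genes at 0.66 (camera adjusted p = 0.0327 and 0.0373; adjusted p = 0.262 and adjusted p = 0.262 with an estimated correlation). The Wnt median was 0.20 without WT CD29lo replicate 1. Their counts over all genes and adjusted over the list alone are given above. Interferon genes in KO stood at -2.27, or -2.24 so raised (camera adjusted p = 5.67e-10; adjusted p = 0.284 with an estimated correlation), with 11 lower over all genes and 17 when adjusted over the list alone. Prolactin and STAT5 genes in KO stood at -0.52 (camera adjusted p = 0.0086; adjusted p = 0.284 with an estimated correlation), with 5 lower over all genes and 6 when adjusted over the list alone, and at -0.15 with every probe set. Matrix and adhesion genes in KO stood at 0.85 (camera adjusted p = 0.00184; adjusted p = 0.419 with an estimated correlation), with 8 higher and 1 lower both over all genes and when adjusted over the list alone, and at 0.38 without KO CD29lo replicate 1. With the fibroblast covariate 3 of the 13 WT lists lost their calls: acute phase genes (0.0723), milk genes (0.279) and fibroblast markers (0.715).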

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

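The tests that weigh explanations for the 3 patterns below (fibroblast markers, cell-cycle genes and luminal progenitor genes) were chosen after their results had been seen. In the planned interaction test 6 gene lists differed between the subpopulations in the genotype contrast by camera with the preset correlation. The median difference, CD29hi minus CD29lo, was -1.05 for cell-cycle genes (camera adjusted p = 2.11e-09), -0.52 for luminal progenitor genes (0.00922), -0.17 for luminal epithelial markers (0.00691) and -0.18 for Notch genes (0.032), or -0.17 for these with groups below the background raised to it. It was 1.03 for genes of the epithelial to mesenchymal transition (0.00633) and 1.59 for fibroblast markers (0.00691). With an estimated correlation these lists had adjusted p = 0.676, or 0.864 for fibroblast markers, and fry called 0 lists. Over all genes 0 members of each passed, and when adjusted over the list alone 8 cell-cycle genes and 0 of the others did. The cell-cycle call alone held whichever array was left out.

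The interaction call of fibroblast markers was lost without KO CD29hi replicate 2 (0.128), KO CD29lo replicate 1 (0.983), WT CD29hi replicate 1 (0.382) or WT CD29lo replicate 2 (0.453). The mesenchymal transition call was lost without KO CD29lo replicate 1 (0.148) or WT CD29lo replicate 2 (0.123). The progenitor call was lost without KO CD29hi replicate 1 (0.0702), KO CD29lo replicate 1 (0.0654), WT CD29hi replicate 2 (0.11) or WT CD29lo replicate 2 (0.0916). The luminal epithelial call was lost without KO CD29lo replicate 2 (0.0519), WT CD29hi replicate 2 (0.173) or WT CD29lo replicate 2 (0.211). The Notch call was lost without KO CD29hi replicate 1 (0.0702), KO CD29lo replicate 2 (0.217), WT CD29hi replicate 2 (0.257), or WT CD29lo replicate 1 (0.0529) or 2 (0.123). It was also lost with the replicate number as a block (0.053), the filter at the 50th percentile (0.11), values raised to 4 (0.155), no filter (0.165), every probe set (0.286) and the mean of probe sets (0.358). With both CD29lo arrays numbered 2 left out, the progenitor (0.0599), luminal epithelial (0.348) and Notch (0.348) calls were lost. With the fibroblast covariate, the mesenchymal transition (0.066) and fibroblast (0.946) calls were lost.

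A probe set outside the tested genes also differed by genotype. Its annotation lists 2 genes, so none is named here. It was lower in KO by a log2 fold change of -5.85 in CD29lo (limma adjusted p = 0.0179) and -5.05 in the averaged contrast (limma adjusted p = 0.00346). In CD29hi it stood at -4.245 and did not pass (limma adjusted p = 0.117). It was tested among 6254 probe sets without a single gene. Its 4 WT values lay between 9.1 and 11.23 and its 4 KO values between 4.59 and 6.16.

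Fibroblast markers were higher in CD29lo than in CD29hi, with medians of 4.01 in WT and 2.59 in KO (3.92 and 2.40 with groups below the background raised to it). The endothelial markers did not rise with them: their difference of -0.0925 in WT lay outside the fibroblast list's interquartile range of 2.38 to 5.29. Nor did pericyte (-0.235 in WT and 0.09 in KO), adipocyte (0.222 and -0.09) or blood cell markers (0.42 and 0.29) rise as far. These values do not decide whether the share of epithelial cells as a whole was lower. The cells were sorted as LIN-, and a cell type removed by that gate could not rise as the share fell. Stromal cells among the CD29lo cells are a candidate source, although a CD24 gate should leave such cells out. In both genotypes 16 of 19 markers, Dcn and Col1a2 included, were higher in CD29lo. That count restates the pattern and does not separate its sources. Expression by the CD29lo epithelial cells cannot be told apart from stromal cells, since cells were not measured singly. The list's median differed by 2.35 between the WT CD29lo arrays and by 3.31 between the KO CD29lo arrays. It was higher in replicate 2 than in replicate 1 in every group. At either number KO CD29lo lay below WT CD29lo (-0.697 against 1.02, and 2.61 against 3.37). The labels do not tie the number to a paired set. Whether the lower median in KO CD29lo follows the sort or the genotype thus cannot be told.

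Cell-cycle genes were lower in KO than in WT within CD29hi, with a median of -1.25. Camera with the preset correlation gave an adjusted p of at most 6.48e-10 whichever array was left out. That correlation (0.01) treats the members as nearly independent, so this p does not decide whether a single array made the size. With each gene centred on its mean, the list's median was 0.611 and 1.52 in the WT CD29hi arrays. It was -0.283 and -0.534 in the KO CD29hi arrays. The direction thus did not rest on a single array, but part of the size may rest on WT CD29hi replicate 2, which stood highest. Values below the background do not account for the size. Only 1 of 35 members had such a group, and the median stayed at -1.25 with it raised to the background. Dim values above the background remain a candidate cause of part of the size. The 14 members with a mean log2 of 7 or more had a median of only -0.43, though 12 of them were below 0 (interquartile range -0.85 to -0.28). Genotype cannot be told apart from the mice or the sort of a pool, since each group has 2 arrays, all from mice of its own genotype. With an estimated correlation the list had camera adjusted p = 0.534, a test that does not measure variation between pools.

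Luminal progenitor genes were lower in KO than in WT within CD29hi, where they are dimmer than in CD29lo. Carry-over of the whole CD29lo gate into the WT CD29hi sort was examined in genes over 2-fold higher in KO CD29lo than in KO CD29hi. By the 8 such progenitor genes it would need a share of 17.1%, and would shift 8 hormone-sensing genes by a median of -1.41. Their observed median shift was -0.13, with an interquartile range of -0.66 to 0.31. The KO CD29hi values that picked the genes also enter the shift. The 8 progenitor genes had a median of -1.7, against -0.655 for all 17. The share and the predicted shift may thus be too large. The same rule picked both sets, however. The share needed ran from 9.99% to 39% over the progenitor genes and from -11.5% to 7.81% over the hormone-sensing genes. For these genes the values argue against carry-over of the whole gate as the only source. Carry-over of luminal progenitors alone cannot be told apart from lower expression within basal cells, since the list is made of their markers. With an estimated correlation the list had camera adjusted p = 0.539, which does not bear on that question. Progenitor carry-over and lower expression within basal cells thus both remain open.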

How the results depend on the processing

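Values raised to at least 4, both CD29lo arrays numbered 2 left out and the fibroblast covariate were chosen after the data had been seen. The causes of the shifts below were not tested, except where fewer arrays or genes make them. A list's direction was read from its median; this replaced camera's direction after first results had been seen. By the median, fibroblast markers in KO against WT in CD29lo reversed to 0.425 without KO CD29lo replicate 1 and to 0.027 with the fibroblast covariate, which removes them by construction. Their genes Pdgfra and Serpinf1 reversed to 0.28 and 0.135 without the same array, and matrix genes in WT to -0.015 without WT CD29lo replicate 1. The other ends of these ranges were -2.98 for the fibroblast list, -3.02 for Pdgfra and -2.065 for Serpinf1 without KO CD29lo replicate 2, and 0.948 for matrix genes without WT CD29lo replicate 2. By camera's direction, the fibroblast interaction also reversed, with medians of 0.1 without KO CD29lo replicate 1 and 0.171 with the covariate, and the matrix list did not.

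For Cebpb the sign held in every fit. It no longer passed without a trend (-3.11 in CD29hi, -2.945 in CD29lo), with the mean of its probe sets (-2.032 and -2.198), and in CD29lo with only the arrays compared (-2.945) or both arrays numbered 2 left out (-2.6). Leaving out 1 array gave -3.5 to -2.72 in CD29hi, -3.12 to -2.77 in CD29lo and -3.222 to -2.832 averaged.

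The count in CD29hi (2) became 1 without a trend, 1 at the 50th percentile, 0 with the mean of probe sets, and 4 with the covariate, only the arrays compared, or values raised to 4. In CD29lo (2) it became 1 without a trend, 1 at the 50th percentile, 0 with only the arrays compared or both arrays left out, 7 with the covariate and 5 with values raised to 4. The averaged count (10) became 4 without a trend, 2 at the 50th percentile, 5 with both arrays left out and 16 with the covariate. In WT the count between gates (1196) became 785 without a trend and 605 with the covariate. Leaving out 1 array gave 0 to 3 in CD29hi, 0 to 2 in CD29lo, 3 to 21 averaged, 0 for the interaction, 512 to 1383 between gates in WT and 722 to 1913 in KO.

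The labels do not tie the replicate number to a paired set, so the number was not taken as a pair. The deviations of equally numbered arrays correlated between 0.00563 and 0.321, or -0.0129 and 0.493 among bright genes. Both highest values belonged to KO CD29lo with WT CD29lo, so an effect shared by equal numbers is not excluded there. With the number as a block the averaged count was 16, and 3 in either gate. Of the 6 averaged lists 4 then passed, and 5 of the 6 in CD29lo. The pool of glands as a random block (correlation 0.0172) gave 10.

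The correlation of the genotype contrasts (0.159) was 0.127 with every probe set, 0.113 with both arrays left out, 0.127 with the covariate, 0.182 at the 50th percentile and 0.101 without a filter, and 0.106 to 0.154 without 1 array.

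Lists passing became 0 with an estimated correlation in all 6 contrasts, and 0 with fry in the 4 that involve genotype. In CD29hi (4) every probe set gave 7, in CD29lo (6) the 50th percentile gave 3 and the mean of probe sets 1, none of them lower, and averaged (6) that mean gave 3. Without 1 array they were 4 to 8 in CD29hi, 3 to 5 in CD29lo, 2 to 6 averaged, 1 to 6 for the interaction, 10 to 13 in WT and 9 to 12 in KO.

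In the counts for named genes, a gene that passed in neither fit counts as kept, so they do not measure how often calls held. The losses of single genotype calls are given above. Of 2589 other values of named genes, 2484 kept direction and side of the threshold, 78 no longer passed and 27 newly passed. Without 1 array 1529 of 1648 did, 110 no longer passed, 7 newly passed and 2 reversed. For lists 474 of 539 did in other settings, with 64 no longer passing and 1 reversed, and 298 of 368 without 1 array, with 68 and 2. Lists were not run with the random block, nor the averaged, interaction and correlation results with only the arrays compared. Signal over background limits the dimmest genes.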

Other observations

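The test in this part was fixed before its result was seen. Chance was examined for the 10 genes called between KO and WT averaged over both subpopulations, with subpopulation as a term in the limma fit. Of the 35 splits of the 8 arrays into 4 and 4, 34 could be fitted, since the remaining split is the subpopulation itself. The real split gave 10 genes and the highest of the other splits gave 1, so 1 of 34 splits, the real one, gave as many. The balance of the splits was looked at after this result: 16 of these splits place 3 CD29hi arrays against 1 and so are partly tied to the subpopulation term. Only 18 splits, the real one included, are balanced over the subpopulations, where the highest other also gave 1. These 18 are too few for a share under 0.05. The mice behind each array are not given, and arrays of both gates may come from the same pool. The splits would then treat arrays that share mice as separate, so they do not decide on chance. Genotype is not separated here from other differences between the wildtype and knockout mice.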
